A study of Ovis aries and Bos taurus with 15 samples.

How the data were processed

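Gene expression was measured in 15 samples on Affymetrix bovine arrays, 1 array per sample, in 3 groups of 5: bovine cells that the labels call BAEC, ovine cells called PAEC given the DMSO vehicle, and ovine PAEC given GW9662 at 5 µM for 24 h. Per the labels' protocols, cells were grown in DMEM with 10% FBS, total RNA was extracted with a column kit, and biotin-labelled cRNA was made from 1 µg of RNA. The deposited values are log2 expression values of 24128 probe sets, made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalises the arrays and summarises the probes of each probe set. The values ran from 0.899 to 14.07, with a median of 3.22, and 45.9% of the probe sets tested had a mean under 3 over the 15 arrays. The deposited values record no signal over background, so a low value cannot be told from no expression. A difference against a group with a mean under 3 is therefore a lower bound in signal. Between bovine and ovine arrays, a low ovine value could also come from poor match of sheep RNA to bovine probes. Such a difference bounds no difference in expression.

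The 112 control probe sets were left out of the tests, which left 24016. In the platform annotation given, 13292 of these had 1 gene symbol, 86 had several and 10638 had none. Only probe sets with 1 symbol were named, and they covered 9155 genes. Where several probe sets named a gene, the brightest over the arrays of the fit stood for it, and another probe set past the threshold in the opposite direction is stated where the gene is described.

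Both comparisons, GW9662 against vehicle and bovine control against ovine vehicle, were fitted on their own 10 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 24016 probe sets and a threshold of 0.05. Adjusted p-values come from limma unless another test is named. Log2 differences are given with their standard error, and group means with their SD over 5 arrays. Of 28 gene lists for pathways and cell type markers, holding 913 genes of which 727 were measured, 27 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. Camera, which compares a list with the other genes, was repeated with an estimated correlation. The fry test asks a different question, whether the genes of a list move on balance one way, and compares them with no other genes. The p-values of each were adjusted over the 27 lists. Counts "adjusted over the list alone" apply the adjustment to a list's own genes. Measures with 1 value per array were compared by two-sided exact permutation tests, whose smallest p with 5 against 5 arrays is 0.00794. As a measure of RNA quality, the difference between 3′ and 5′ probe sets was averaged over 6 control transcripts on each array.

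The genes to be named, the lists, the tests and most other settings were fixed before the data were examined. The rule took up to 12 genes per direction for GW9662 and up to 6 per direction for the bovine and ovine controls, those of largest change among genes past the threshold whose groups did not overlap. It also took up to 4 members of each list past the threshold with the smallest p, or up to 2 where none passed, with lists that camera did not call free to be given by count alone. A further 29 genes of PPARγ signalling, vascular tone, redox balance and cell identity were to be given for GW9662 whatever their values, of which CPT1A and SLC7A11 had no named probe set. Genes given outside this rule are said to have been chosen after their values were seen.

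The fits were tested on simulated data with known changes. For GW9662 against vehicle, with 24016 probe sets, 73% of changes of 0.5 and 93% of changes of 1 on the log2 scale were recovered, with 7 false calls. For the bovine and ovine controls the shares were 67% and 92%, with 8 false calls. The changed probe sets were drawn from all 24016, dim ones included, and recovery was not split by brightness. Spread can be small among dim probe sets, as for ACTA2 (SD 0.006 in both ovine groups). Recovery among brighter genes may therefore be lower than these shares. A list shifted by 0.3 on the log2 scale was recovered in both comparisons, with 0 false list calls from camera. The simulated genes varied independently of each other, so these false calls do not cover genes that vary together. Among 100 splits of the real arrays, the real one included, 14 gave 5 or more lists for GW9662. For the controls 39 gave 4 or more.

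The other settings fixed at that point were array centring, a second quantile normalisation, a filter on dim probe sets, a trended and robust variance, array weights, a fit of all 15 arrays, a replicate block, leaving out each array, a limit on the difference between species, a plain test for each probe set, 1 probe set per gene, a fold threshold of 2, and other list tests. A fit with the 3′ minus 5′ difference as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9.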

Results

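RNA from endothelial cells was profiled on 15 arrays carrying bovine probes, in 3 groups of 5. Ovine PAEC, the pulmonary cells of the study's title, received GW9662 or the DMSO vehicle, and bovine cells labelled BAEC formed a further control group. GW9662 is an irreversible antagonist of PPARγ, a nuclear receptor that switches on genes of fatty acid handling. Medians of the log2 values ran from 3.18 to 3.27 between arrays. The arrays carry no depth, and their number limits the precision. Nothing in the labels says that the replicates were separate cultures or animals, so p-values measure only the spread between samples, which could be technical.

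The first comparison asked which genes changed when the PPARγ antagonist was given to ovine PAEC for 24 h. SHOC2, a scaffold of the RAS and ERK pathway, rose by 0.96 on the log2 scale (SE 0.11, adjusted p = 0.0165, 5 arrays per group). SLC30A1, the zinc exporter of the plasma membrane, rose by 0.87 (SE 0.098, adjusted p = 0.0165). NQO1, a quinone reductase of the antioxidant response, rose by 0.67 from 6.61 ± 0.18 to 7.29 ± 0.15 (adjusted p = 0.0495). CCNA2, the cyclin of S phase and mitotic entry, rose by 0.62 from 5.31 ± 0.070 to 5.93 ± 0.12 (adjusted p = 0.0111). The falls were smaller: TM4SF18, a transmembrane protein, fell by 0.43 from 7.49 ± 0.067 to 7.06 ± 0.054 (adjusted p = 0.00696), and REXO1, an RNA exonuclease homologue, fell by 0.41 (SE 0.038, adjusted p = 0.00919). For each of these genes all 5 GW9662 arrays lay on the same side of all 5 vehicle arrays.

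Other genes that rose were TNFRSF6B, a decoy receptor for FAS ligand (0.83, mean 3.37 against 2.54), the splicing factor SRSF1 (0.64), TC2N (0.45), SGO2, which guards centromeric cohesion (0.45), MMD (0.44), HMMR, a hyaluronan receptor that also binds the spindle (0.42), the tetraspanin TSPAN12 (0.33) and SUCLA2, a subunit of succinyl-CoA ligase (0.32). Their adjusted p lay between 0.0119 and 0.0455. Genes that fell were SARDH, the mitochondrial sarcosine dehydrogenase (-0.37), AURKAIP1, which binds the Aurora A kinase (-0.26), the zinc finger repressor ZNF746 (-0.24), the lactate exporter SLC16A3 (-0.23) and NME7 (-0.18), with adjusted p from 0.0117 to 0.0462. In all 13 genes, too, the 5 GW9662 arrays and the 5 vehicle arrays did not overlap. Another SRSF1 probe set rose by 0.61 (adjusted p = 0.0419). The remaining SRSF1 probe set was at 0.11 and did not pass (7.84 with GW9662 against 7.73 with vehicle, adjusted p = 0.261). The other TM4SF18 probe set gave 0.04 (adjusted p = 0.871).

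**Figure D1:**
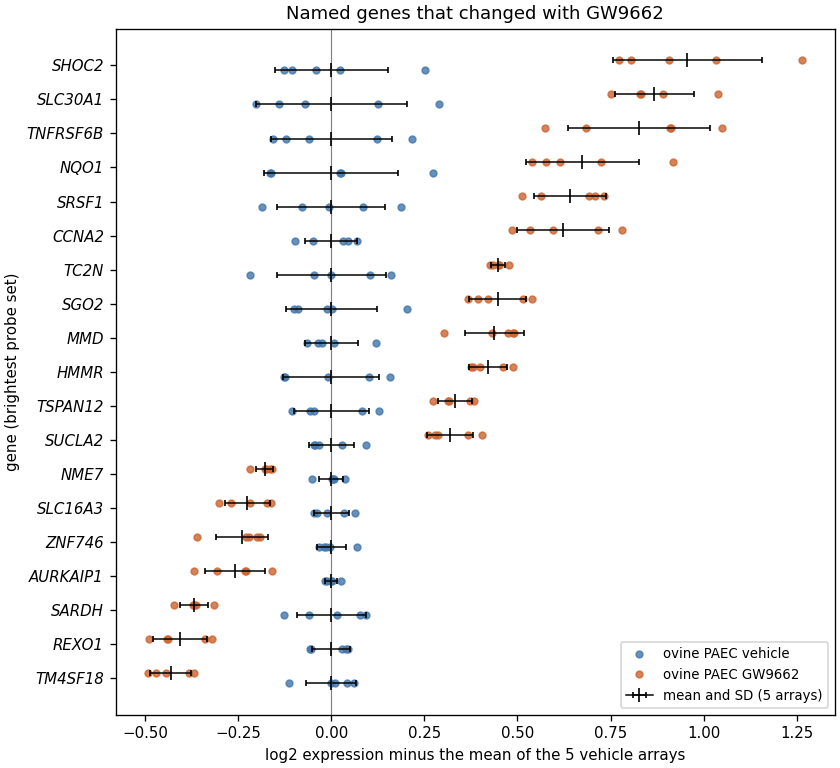
Log2 expression of the 19 named genes that changed with GW9662, each point 1 array, plotted as the difference from the mean of the 5 vehicle arrays, with black marks for the mean and SD. The GW9662 arrays of SHOC2 centre on 0.96 above vehicle and those of TM4SF18 on -0.43, and in every gene shown the groups do not overlap.

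In all, 44 of 24016 probe sets changed with GW9662, 35 higher and 9 lower (79.5% higher), and they held 30 named genes and 12 probe sets without a name. When only the brightest probe set of each of 9155 genes was tested, limma called 30, of which 20 were among the 44. The rest of the named genes among the 44 were called on a dimmer probe set, while their brightest did not pass. With the replicate number as a block limma called 0 probe sets (3205 at an unadjusted p under 0.05) and 0 of the 19 genes named above. The 15 that changed at least 1.5-fold all rose. The 3 that changed at least 2-fold, chosen after their values were seen, were a probe set without a name (1.51, SE 0.21), a second probe set of HMMR (1.21, SE 0.16) and a probe set of AP2B1, a subunit of the clathrin adaptor (1.12, SE 0.16), each with groups that did not overlap. That AP2B1 probe set was dim, at 3.97 with GW9662 and 2.85 with vehicle. The brightest AP2B1 probe set did not pass. Groups did not overlap in any of the 44, nor in 14.6% of all probe sets, where chance gives 0.794%. The share higher was 91.0% of 67 probe sets (61 against 6) with each array centred on its median and 61.3% of 62 (38 against 24) after a second quantile normalisation. At an unadjusted p under 0.05, limma gave 5141 probe sets, 1650 higher and 3491 lower, a balance that turned to 2870 higher and 518 lower with centring and was 1425 higher and 1799 lower after quantile normalisation.

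The count depended on single arrays and was 18 without vehicle replicate 2, 9 without vehicle replicate 5, and 23, 22, 20 and 17 without GW9662 replicates 1, 2, 4 and 5. The 15 probe sets of at least 1.5-fold became 6 and 2 without vehicle replicates 2 and 5, 28 without GW9662 replicate 3, and 4, 6, 5 and 5 without GW9662 replicates 1, 2, 4 and 5. Of the 19 genes named above, CCNA2, TM4SF18 and REXO1 stayed past the threshold in all 10 such fits and 7 others in 6 to 9 of them. The remaining 9, TNFRSF6B, TC2N, AURKAIP1, SGO2, HMMR, TSPAN12, ZNF746, SLC16A3 and NQO1, stayed in 1 or 2 of the 10, with adjusted p of up to 0.141 (NQO1 without GW9662 replicate 4). Without vehicle replicate 5, 3 of the 19 stayed. The measure of RNA quality moved with the treatment: the 3′ minus 5′ difference was 1.18 ± 0.085 in vehicle arrays and 0.956 ± 0.074 in GW9662 arrays, without overlap (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 arrays can give). Of its 6 control transcripts EF1A and cyclophilin were lower with GW9662 (exact permutation adjusted p = 0.0238 each), eIF4E and GAPDH gave 0.0952 and 0.107, and actin (-0.14 against -0.15, adjusted p = 0.548) and GST (-0.89 against -0.92, adjusted p = 0.486) had means no lower than with vehicle. In EF1A (-1.45 with GW9662 against -1.12), actin and GST the 3′ probe sets read lower than the 5′ ones in both groups. How well the mean over the 6 transcripts records RNA quality is therefore uncertain. With the mean as a covariate 0 probe sets passed in limma, with 1312 at an unadjusted p under 0.05.

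Cell cycle genes were shifted upward as a group. Of 42 measured, CCNA2 rose, 0 fell and 41 did not pass, 33 values were positive, and the median was 0.15 on the log2 scale (camera adjusted p = 1.9e-08). The adjusted p was 0.210 with an estimated correlation, and 10 genes rose when adjusted over the list alone. The median was 0.09 after quantile normalisation. Zinc finger and chromatin genes, regulators of transcription and mRNA decay, were called higher, with 17 of 24 values positive and a median of 0.09 (camera adjusted p = 0.00489, adjusted p = 0.463 with an estimated correlation). None passed singly (limma; 4 at an unadjusted p under 0.05), with 2 rising when adjusted over the list alone, and ZFP36L2, which speeds mRNA decay, was at 0.30 (adjusted p = 0.112) and the chromatin remodeller SMARCA2 at 0.20 (adjusted p = 0.188). That median was 0.02 without vehicle replicate 1, the array farthest from its group, 0.15 without vehicle replicate 3, 0.06 without GW9662 replicate 2, 0.03 with array weights and -0.10 with the 3′ minus 5′ covariate. The call was lost with centring (median 0.13, adjusted p = 0.118), quantile normalisation (0.03, adjusted p = 0.254), dim probe sets left out (0.11, adjusted p = 0.0922) and the covariate (adjusted p = 0.672). Between the same arrays the 3′ minus 5′ difference was 0.956 with GW9662 against 1.18 with vehicle.

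Camera called genes of oxidative phosphorylation, ribosomal proteins and endothelial markers lower. Of 54 oxidative phosphorylation genes 46 values were negative, with a median of -0.09 (camera adjusted p = 0.000155, adjusted p = 0.409 with an estimated correlation), and 7 fell when adjusted over the list alone. COX5B and CYC1, parts of complexes of the respiratory chain, were at -0.16 (adjusted p = 0.0913) and -0.22 (adjusted p = 0.112). Of 61 ribosomal protein genes 53 values were negative, with a median of -0.07 (camera adjusted p = 0.000207, adjusted p = 0.557 with an estimated correlation). RPS6 was at -0.17 and RPS15A at -0.08 (adjusted p = 0.217 each). The call was lost with quantile normalisation (median -0.02, adjusted p = 0.451) and with the 3′ minus 5′ covariate (median -0.05, adjusted p = 0.103). Of 25 endothelial markers 22 values were negative, with a median of -0.08 (camera adjusted p = 0.00489, adjusted p = 0.409 with an estimated correlation), and 6 fell and 1 rose when adjusted over the list alone. Their call was lost with the mean over the probe sets of each gene (median -0.04, adjusted p = 0.0955), and their median was -0.14 with the covariate. Endothelial list means per array, tested after the results were seen, overlapped between groups (exact permutation p = 0.175, adjusted p = 0.295). With centring the medians of these 3 lists were -0.05, -0.02 and -0.04, each still called. The adhesion molecule MCAM was at -0.19 (adjusted p = 0.178), the guidance receptor ROBO4 at -0.18 (adjusted p = 0.205) and PECAM1, of endothelial junctions, at -0.15 (adjusted p = 0.217). Singly, no gene of these 3 lists passed in limma, with 19, 19 and 9 lower at an unadjusted p under 0.05, and the 3′ minus 5′ difference between these arrays was 0.956 against 1.18. The 5 calls stood among 27 lists tested, of which camera called 0 with an estimated correlation (1 at an unadjusted p under 0.05). The fry test, which asks whether a list's genes move one way and compares them with no other genes, called 3 of the 5 and gave 0.208 for the zinc finger and 0.0512 for the ribosomal genes.

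**Figure D2:**
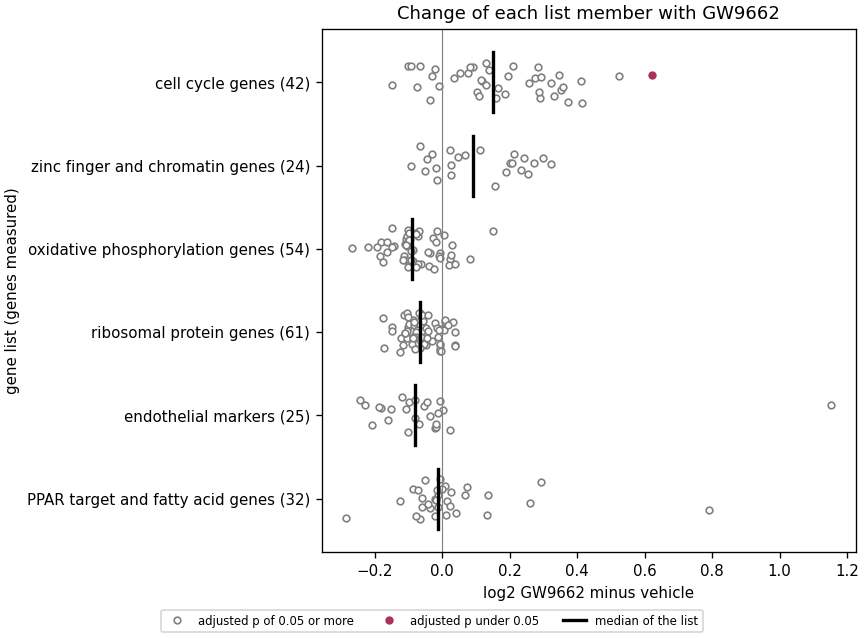
Log2 difference between GW9662 and vehicle for each measured gene of 6 lists, with the list median as a black bar and filled points for adjusted p under 0.05. The median of the cell cycle genes is at 0.15 and that of the oxidative phosphorylation genes at -0.09, while CCNA2 is the one filled point. Direction of the zinc finger median turns to -0.10 with the 3′ minus 5′ covariate.

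**Figure D3:**
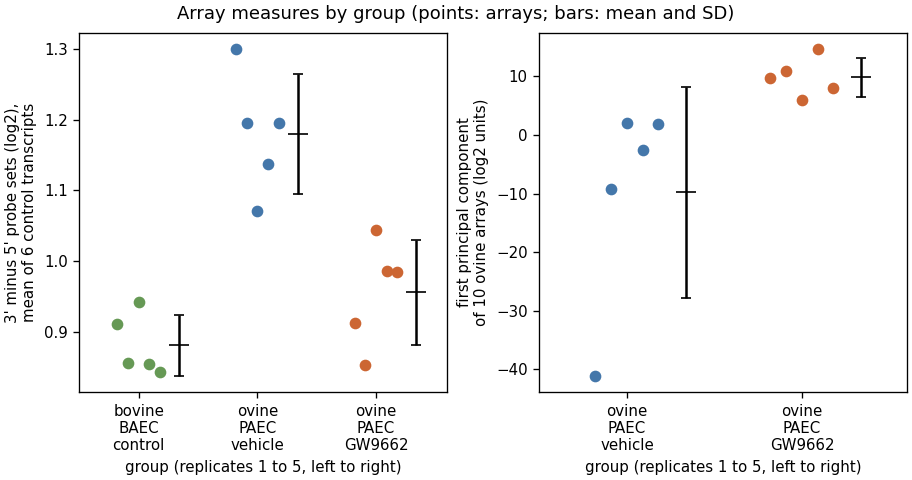
Difference between 3′ and 5′ probe sets of 6 control transcripts (left, log2) and first principal component of the ovine arrays (right), each point 1 array and the bars mean and SD of 5 arrays. Vehicle arrays lie at 1.07 or more on the left and GW9662 arrays at 1.04 or less, and vehicle replicate 1 lies at -41.1 on the right.

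PPARγ and its known target genes were not among the changes. PPARG was near the floor of the arrays, at 2.79 ± 0.020 with GW9662 and 2.82 ± 0.028 with vehicle (log2 difference -0.03, adjusted p = 0.268). FABP4, a fatty acid carrier and PPARγ target, was among the brightest genes at 12.5 in both groups (log2 difference -0.02, SE 0.049, adjusted p = 0.769), and the targets ANGPTL4, PDK4 and PLIN2 were at 0.01, 0.01 and 0.14 (adjusted p = 0.953, 0.821 and 0.261). PDK4 was dim, at 3.13 with GW9662 and 3.12 with vehicle, so its value does not show whether it responded. The fatty acid receptor CD36 was at 0.79 with an SE of 0.24 on a dim probe set, 3.82 against 3.02 (adjusted p = 0.217). Of 32 PPAR target and fatty acid genes 0 passed in limma, with 7 at an unadjusted p under 0.05 (4 higher and 3 lower), and 1 rose and 1 fell when adjusted over the list alone. These were led by ACSL1 at 0.13 and SCARB1 at -0.28 (adjusted p = 0.123 and 0.166). The list's median was -0.01, its mean 0.03, and camera gave an adjusted p of 0.835. Of the other receptors, PPARD was at -0.17 (adjusted p = 0.234), PPARA at -0.07 (0.261), RXRA at -0.08 (0.316) and RXRB at 0.09 (0.496). PPARA lay near the floor, at 2.81 with GW9662 and 2.88 with vehicle, and RXRB was dim, at 3.26 and 3.17.

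Genes of vascular tone did not pass. The nitric oxide synthase NOS3 was at -0.10 (adjusted p = 0.372), endothelin EDN1 at -0.06 (0.262), its receptor EDNRB at -0.04 (0.218), prostacyclin synthase PTGIS at 0.07 (0.453) and the BMP receptor BMPR2, mutated in heritable pulmonary hypertension, at 0.22 (0.266). EDNRB lay at the floor of the arrays, at 2.58 with GW9662 and 2.62 with vehicle. The brightest probe set of CAV1, the caveolin that binds NOS3, was at -0.06 (adjusted p = 0.393), whereas its other probe set rose by 0.54 (SE 0.079, adjusted p = 0.0462), so the probe sets disagree. VEGFA was at -0.04 (adjusted p = 0.899), and its receptor KDR at 1.15 with an SE of 0.35 on a dim probe set, 3.79 against 2.64 (adjusted p = 0.217). Of the redox genes other than NQO1, HMOX1 was at 0.25 (adjusted p = 0.217), CAT at 0.10 (0.25), SOD2 at 0.09 (0.504) and SOD1 at 0.01 (0.911). The endothelial cadherin CDH5 was at -0.12 (adjusted p = 0.257), VWF and the smooth muscle actin ACTA2 were at the floor of the arrays with -0.02 and -0.01 (0.251 and 0.588).

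Camera called none of the other 22 lists with GW9662 (adjusted p of 0.0530 or more), and in 9 of them the median, the mean and the test differed in sign. Of these 22 lists fry called 8, each downward: inflammation and adhesion (adjusted p = 0.00369), nitric oxide and vasoactive (0.0112), interferon response (0.0234), epithelial and mesothelial (0.0290), fibroblast (0.0290), leukocyte (0.0370), erythroid and platelet (0.0371) and extracellular matrix genes (0.0490). Their medians lay between -0.020 and -0.042. Centring moved the median difference over all probe sets from -0.016 to 0.027. Fry compares a list with no other genes and was not repeated with centring, so these downward calls may depend on the scaling. Of 28 nitric oxide and vasoactive genes 0 passed in limma (8 at an unadjusted p under 0.05, 1 higher and 7 lower), 1 fell when adjusted over the list alone, and RAMP2, which pairs with the adrenomedullin receptor, was at -0.23 (adjusted p = 0.0770). Of 31 inflammation and adhesion genes 0 passed (13 at an unadjusted p under 0.05, 3 higher and 10 lower), 1 rose and 2 fell when adjusted over the list alone, with VCAM1 at -0.29 (adjusted p = 0.0627) and the macrophage growth factor CSF1 at -0.36 (0.123). In camera the adjusted p for markers of other cell types was 0.0542 for erythroid cells and platelets, 0.0733 for leukocytes, 0.128 for epithelium and mesothelium, 0.396 for fibroblasts and 0.835 for smooth muscle.

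The second comparison set the bovine BAEC controls against the ovine PAEC given vehicle. The basement membrane collagen COL15A1 was higher in bovine cells by 8.17 on the log2 scale (SE 0.10, 10.9 ± 0.043 against 2.69 ± 0.24, adjusted p = 1.2e-10). Coagulation factor F5 was higher by 6.33 (SE 0.086, 2.50 in ovine cells, adjusted p = 1.5e-10). VCAM1, which binds leukocytes, was lower by a log2 difference of -6.97 (SE 0.20, 2.41 ± 0.46 against 9.38 ± 0.098, adjusted p = 1.3e-08), and the neutrophil chemokine CXCL2 by -6.74 (SE 0.094, 2.49 in bovine cells, adjusted p = 1.7e-10). The others of largest difference were ADCY2, an adenylyl cyclase (5.86), TPD52 (5.74), the trypsinogen PRSS2 (5.54) and BEX3 (5.18) on the bovine side, and LOC514170 (-7.55), the dermatan sulfate epimerase DSE (-5.71), the inhibitory G protein GNAI1 (-5.35) and muscle creatine kinase CKM (-5.22) on the ovine side. In each, all 5 bovine arrays lay on the same side of all 5 ovine arrays. In 8 of these 12 genes the lower group had a mean under 3, at the floor of the arrays: the first 4 named, ADCY2 (2.77), PRSS2 (2.09), BEX3 (2.49) and CKM (2.57). Their differences are lower bounds in signal, and the order by size is set in part by that floor. For COL15A1, F5, ADCY2, PRSS2 and BEX3 the low group was ovine. Poor match of sheep RNA to bovine probes could also give those low values, so these differences bound no difference in expression.

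Sterol and lipid synthesis genes were higher in the bovine cells: of 28 measured, 22 were higher, 0 lower and 6 did not pass, with a median of 1.45 (camera adjusted p = 3.5e-15, adjusted p = 0.00688 with an estimated correlation). The fatty acid desaturases FADS2 and SCD were higher by 4.16 and 2.89, and HMGCS1 and SQLE of cholesterol synthesis by 2.86 and 2.11. The value of FADS2 is a lower bound in signal only, from 2.27 in ovine cells. Of 42 cell cycle genes 33 were higher, 2 lower and 7 did not pass, with a median of 0.82 (camera adjusted p = 1.2e-11, adjusted p = 0.0731 with an estimated correlation). The mitotic cyclin CCNB1 was higher by 1.35, CCNA2 by 1.20, the spindle protein TPX2 by 0.97 and the replicative helicase subunit MCM7 by 0.94. Of 31 inflammation and adhesion genes 13 were lower, 3 higher and 15 did not pass, with a median of -0.13 and a mean of -1.16 (camera adjusted p = 0.00109, adjusted p = 0.0316 with an estimated correlation). The median was -0.84 with dim probe sets left out. Besides VCAM1 and CXCL2, the selectins SELE and SELP were at -4.71 and -3.94 and the chemokine CXCL8 at -3.45. Of 24 zinc finger and chromatin genes 14 were higher, 3 lower and 7 did not pass, with a median of 0.27 (camera adjusted p = 0.0253, adjusted p = 0.622 with an estimated correlation). That call was lost with centring (median 0.30, adjusted p = 0.0639), quantile normalisation (0.25, adjusted p = 0.0709) and dim probe sets left out (0.28, adjusted p = 0.172). In that list the repressor ZEB1 was higher by 0.83, ZFP36L1 of mRNA decay by 0.52, the polycomb subunit EED by 0.28, with 4 of its 22 other probe sets called lower, and SMARCA2 was at -0.51. Beside each of the 4 lists stood the 3′ minus 5′ difference, 0.881 ± 0.043 in bovine and 1.18 ± 0.085 in vehicle arrays (two-sided exact permutation p = 0.00794, the smallest possible). Its probe sets are bovine too, so match of sheep RNA to them could also move it between these groups.

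**Figure D4:**
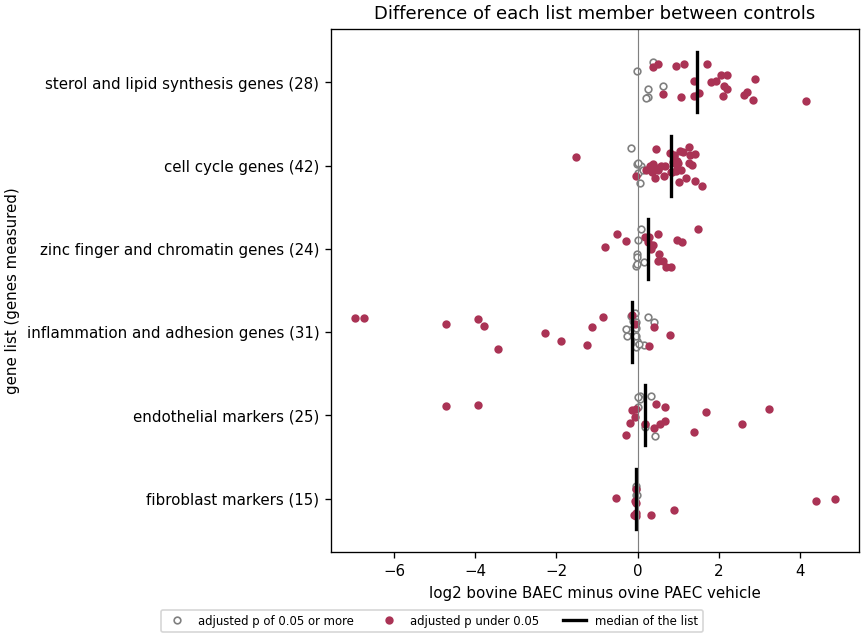
Log2 difference between bovine BAEC and ovine PAEC vehicle arrays for each measured gene of 6 lists, with the list median as a black bar and filled points for adjusted p under 0.05. The median of the sterol and lipid synthesis genes is at 1.45 and the inflammation and adhesion genes reach down to -6.97.

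In all, 10860 probe sets differed, 3740 higher and 7120 lower in bovine cells (34.4% higher), and 1304 differed at least 2-fold, 728 higher and 576 lower. Groups did not overlap in 53% of probe sets, where chance gives 0.794%. The share higher was 57.9% of 6455 probe sets with each array centred on its median and 47.4% of 6802 after a second quantile normalisation. Across all probe sets the group means correlated with an r of 0.980, where probe sets are not independent replicates, and 94.6% lay within 1 log2 unit. The probes are bovine, species and cell source differ together between these groups, and the labels do not say whether the bovine cells received DMSO, so no difference can be assigned to any of these.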

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

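The counts of gene lists under other splits, the list means per array, the fit with the 3′ minus 5′ covariate, the leave-one-out spread set beside its ratios, the matched lists under that spread and the count of calls without vehicle replicate 1 were chosen only after the results were seen. The spread was added once the ratios were known, and it left open how much of the cell cycle shift RNA quality made up.

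Among 44 probe sets that changed with GW9662, 35 rose and 9 fell. Of 100 splits of the 10 ovine arrays 1, the real one, gave as many as 44 probe sets (highest other 6), and 1 gave as many as 15 of at least 1.5-fold (highest other 1). Both counts argue against a chance split of these samples. Chance differences between cultures were not tested, since the replicates could be technical. Nor was chance tested for the balance of direction, which at an unadjusted p under 0.05 was 1650 higher and 3491 lower but 2870 and 518 with centring. The 9 arrays without vehicle replicate 1 called 43 probe sets, 32 higher and 11 lower. Of these 27 were among the 44, and 12 of the 19 named genes stayed past the threshold. The count argues against that array as the source of the number of calls, but not of the calls that were lost. The median of 0.962 of the log2 change held without it decides nothing, since no called probe set fell below 0.860 as any 1 array was left out. With the 3′ minus 5′ covariate the median ratio was 0.818 (quartiles 0.679 to 0.976, and 0.778 to 0.916 as each array was left out). Probe sets were called in part for a small spread within groups. That spread allowed a median of 0.375 at the lowest, and only with residuals in full correlation with the covariate. The ratio therefore does not decide whether RNA quality was the whole source. The measure differed between groups even without vehicle replicate 1 (exact permutation p = 0.0159). All calls ended under that covariate, which correlated with treatment at r = -0.844: the changes shrank by that ratio, the median SE of the called probe sets grew from 0.0565 to 0.103 and 7 residual degrees of freedom were left, contributions that were not separated, so a part played by RNA quality and an effect of GW9662 itself both stay open.

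Cell cycle genes were shifted upward with GW9662, with a median of 0.15, by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.210) nor in the exact permutation test of the list mean per array (adjusted p = 0.107). The list median lay above all of 10000 random lists matched on mean expression (percentile 100, central range -0.03 to 0.06), which argues against a trend with intensity, and it held 0.935 of its size without vehicle replicate 1, which argues against that array. With the 3′ minus 5′ covariate the list stayed above its matched lists (percentile 100, central range -0.13 to 0.00). Camera then gave an adjusted p of 1.8e-06 at the preset correlation, whose call without the covariate was lost at 0.210 when the correlation was estimated. As each array was left out the lowest percentile was 99.99 and the highest camera adjusted p 0.00286. The slope on that measure therefore did not take up the whole shift against other genes. Whether RNA quality did is not decided, since the measure records it uncertainly and correlated with treatment at r = -0.844. The median itself held 0.777, but from 0.435 to 1.43 as each array was left out, lowest without GW9662 replicate 3 and highest without vehicle replicate 1, so the part of its size due to RNA quality cannot be told apart from an effect of GW9662. Chance cannot be excluded for the number of lists shifted: 14 of 100 splits gave 5 or more lists (highest other 7).

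Bovine and ovine control arrays differed in 10860 probe sets. Of 100 splits of those 10 arrays 1 gave as many (highest other 1), which argues against a chance split of these samples for that count. A chance split cannot be excluded for the number of lists called, 4, since 39 of 100 splits gave as many (highest other 7). The mean of each of these 4 lists separated the 5 bovine from the 5 ovine arrays, by 1.504 for sterol, -1.165 for inflammation, 0.658 for cell cycle and 0.303 for zinc finger genes (exact permutation p = 0.00794 each, the smallest possible, adjusted p = 0.0107). For these differences too a chance split of the samples is argued against, while chance differences between cultures were not tested. However, 20 of the 27 lists separated the arrays with the same p, and camera lost the cell cycle and zinc finger calls with an estimated correlation (adjusted p = 0.0731 and 0.622). Leaving out vehicle replicate 1 gave 1299 probe sets of at least 2-fold against 1304 with it, which argues against that array. Pairs of probe sets of 1 gene shared the difference with a Pearson r of 0.573 (bootstrap range 0.465 to 0.666, 848 pairs from 551 genes, which are not independent replicates), a range that spans the value set beforehand as counting against poor match of sheep RNA to bovine probes, so that source cannot be told apart from expression, while species and cell source stay open as untested biological sources. For the difference between GW9662 and vehicle r was 0.235 (bootstrap range 0.161 to 0.308, 847 pairs), so probe sets of 1 gene shared that difference less.

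Single arrays stood apart from the other 4 of their group in 25 of 270 groups of values. Chance flags about 1 in 20 groups, and genes of 1 array set are not independent. The numbers that follow are the gap to the nearest other array as a share of the group's range. Vehicle replicate 1 was lowest on the first principal component of the ovine arrays (-41.1, others -9.22 or more, gap 0.739), deviated most from its group's mean profile (0.227 against at most 0.140, gap 0.865), and was highest for VWF (gap 0.829) and lowest for TGFBI (gap 0.958), both at the floor. Bovine replicate 2 deviated most from its group (0.135 against at most 0.108, gap 0.861), lowest for SMARCA2 (gap 0.777) and highest for TIMP2 (gap 0.867). Vehicle replicate 3 was highest for ANGPTL4 (gap 0.902), VCAM1 (gap 0.716), F5 (gap 0.937) and TAGLN (gap 0.747). GW9662 replicate 4 was lowest for CDH5 (11.1 against 11.4 in the others, gap 0.962), PECAM1 (gap 0.805) and NME7 (gap 0.712). ZNF746 was lowest in GW9662 replicate 1 (gap 0.777) and highest in vehicle replicate 4 (gap 0.716). PPARG was lowest in GW9662 replicate 2 (gap 0.730), BMPR2 in GW9662 replicate 3 (gap 0.719) and RXRB in vehicle replicate 2 (gap 0.810), while SMARCA2 was highest in vehicle replicate 5 (gap 0.714). Among bovine arrays, CKM (gap 0.802) and ADM (gap 0.808) were lowest in replicate 5, S100A4 was highest (gap 0.796) and XDH lowest (gap 0.731) in replicate 3, and ADAMTS1 was highest in replicate 1 (gap 0.731).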

How the results depend on the processing

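The fit with the 3′ minus 5′ covariate was chosen only after the data were seen, and the other settings were planned. The 44 probe sets changed by GW9662 became 67 with array centring, 80 in the brighter part of the probe sets, 26 with a trended and robust variance, 237 with all 15 arrays in the fit, 27 among probe sets within 1 log2 unit between species, 19 with a plain test per probe set, 3 at a fold of 2, 0 with the covariate (limma; 1312 at an unadjusted p under 0.05), and 9 to 62 as each array was left out. Those of at least 1.5-fold, 15, became 35 in the brighter part, 46 with all 15 arrays, 0 with the covariate and 2 to 28 as each array was left out. The 5 lists became 3 after quantile normalisation, 8 with the trended variance, 0 with an estimated correlation in camera (1 at an unadjusted p under 0.05), 11 with fry, which compares a list with no other genes, and 5 to 7 as each array was left out. The smaller counts at a fold of 2 follow from the stricter limit, those within 1 log2 unit and with 4 arrays in a group in part from fewer probe sets or arrays, and for the rest the cause was not tested. The 19 named genes that changed had the same sign under every setting that kept them. Their groups did not overlap, so only centring, quantile normalisation and the covariate could have turned a sign. The zinc finger and chromatin median of 0.09 turned to -0.10 with the covariate, the 1 reversal among called lists and named genes past the threshold in either fit. Named genes that passed in neither fit were not counted. Some of them changed sign, such as ANGPTL4 (-0.06 to 0.08) and VEGFA (-0.13 to 0.08) as each array was left out. The balance of counts turned too: with centring the GW9662 probe sets at an unadjusted p under 0.05 went from 1650 higher and 3491 lower to 2870 and 518, and the calls between the controls from 3740 higher and 7120 lower to 3740 and 2715, or 3657 and 2772 in the brighter part, 3031 and 2365 with the replicate block and 728 and 576 at a fold of 2. The 10860 probe sets between bovine and ovine controls became 6455 with array centring, 6802 after quantile normalisation, 6429 in the brighter part, 4020 as 1 probe set per gene, 1304 at a fold of 2, and 7335 to 10858 as each array was left out. The 4 lists there became 2 with an estimated correlation, 22 with fry, and 4 to 5 as each array was left out. Of 1212 values of the 64 named genes over 19 settings, 1200 stayed past the threshold with the same sign, and the others were of PTPRC, CORO1A and ITGAM. Replicate numbers did not pair the samples: same-numbered GW9662 and vehicle arrays deviated together with r from -0.194 to 0.172, bovine and ovine ones from -0.0968 to 0.0937, and 0 arrays correlated best with their own number. With that number as a block, limma called 0 probe sets for GW9662 (3205 at an unadjusted p under 0.05), 0 of at least 1.5-fold, and 5396 between the controls. The deposited values carry no signal over background, so changes near the floor are the least certain.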

Other observations

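The tests on list means per array, on probe set numbering and on the direction of the vehicle arrays were chosen only after the results were seen.

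Several groups of genes differed between the bovine and ovine controls in both directions, and camera did not call their lists against other genes. Of 29 angiogenesis and Notch genes 10 were higher in bovine cells and 10 lower: the chemokine receptor CXCR4 was at 4.49, the Notch ligand DLL4 at 1.63 and the receptor NOTCH4 at 1.14, while the lymphatic growth factor VEGFC was at -3.09 (camera adjusted p = 0.862, fry 0.00528). Of 25 BMP and TGF-beta genes 8 were higher and 10 lower, with TGFBI at 3.51 and TGFB2 at 1.73, and the BMP targets ID1 and ID2 at -2.40 and -2.14 (camera adjusted p = 0.969, fry 0.680). Of 42 extracellular matrix genes 12 were higher and 20 lower, with the elastic fibre protein FBLN5 at 3.18, the protease ADAMTS1 at 2.55 and the protease inhibitor TIMP2 at -1.83, besides COL15A1 (camera adjusted p = 0.964, fry 1.8e-05). Of 33 antioxidant and oxidase genes 9 were higher and 10 lower, with NQO1 at 2.02 and SOD3, MT2A and XDH at -1.88, -1.63 and -1.15 (camera adjusted p = 0.969, fry 0.0762). Of 22 p53 and cell cycle brake genes 4 were higher and 13 lower, with PLK2 at 2.28 and the cyclin kinase inhibitor CDKN1A, CCNG1 and TP53INP1 at -1.61, -0.77 and -0.56 (camera adjusted p = 0.122, fry 0.000299). The p53 list had 17 negative values and a median of -0.35, below all matched random lists (percentile 0). The means per array of the angiogenesis, BMP, extracellular matrix and p53 lists separated the groups (exact permutation adjusted p = 0.0107 each), those of the antioxidant list did not (0.802). All differences are log2 bovine minus ovine over 5 arrays per group, with adjusted p under 0.05 and no overlap between groups, and the 3′ minus 5′ difference was 0.881 in bovine and 1.18 in ovine arrays. Match of sheep RNA to the bovine probes could also move that last difference.

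Vasoactive and cell type genes also split between the controls. Of 28 nitric oxide and vasoactive genes 7 were higher and 11 lower in bovine cells: GUCY1B1 of the nitric oxide receptor was at 2.53, and PTGIS, the flow-responsive factor KLF4 and the dilator peptide ADM were at -3.91, -3.16 and -1.83 (camera adjusted p = 0.880, fry 0.0123). Of 25 endothelial markers 10 were higher and 7 lower, with PLVAP of endothelial diaphragms at 3.23 and ROBO4 at 1.67 against the selectins SELE at -4.71 and SELP at -3.94 (camera adjusted p = 0.125, fry 0.000900). Of 15 fibroblast markers 4 were higher and 7 lower, with the microfibril and matrix genes FBLN1 at 4.87, MFAP5 at 4.39 and COL1A2 at 0.91, and S100A4 at -0.54 (camera adjusted p = 0.969, fry 2.4e-07). At a limit of 1.5-fold 3 were higher and 0 lower. The fibroblast mean per array was higher by 0.637 in bovine arrays, without overlap (exact permutation adjusted p = 0.0107). Of 14 smooth muscle markers 5 were higher and 4 lower, with TAGLN at 1.83, SMTN at 1.27, MYLK at -0.89 and TPM1 at -0.39 (camera adjusted p = 0.880, fry 0.0784). Of 14 leukocyte markers 1 was higher and 5 lower: the endotoxin receptor CD14 was at -4.42 (2.27 against 6.69), while PTPRC, CORO1A and ITGAM differed by at most -0.09 at the floor of the arrays, calls that were lost with quantile normalisation (camera adjusted p = 0.128, fry 1.1e-05). The values of TGFBI, SOD3 and CD14 are lower bounds in signal, since their lower group had a mean under 3. For TGFBI that group was ovine, where poor match of sheep RNA to bovine probes could also give the low value.

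A hypothesis that the shifts of whole lists with GW9662 hold between arrays was tested on list means per array. Of 27 lists 2 separated the 5 GW9662 from the 5 vehicle arrays, the cell cycle genes (difference of means 0.173) and the aryl hydrocarbon receptor genes (0.0755, a list that includes NQO1), each with a two-sided exact permutation p of 0.00794, the smallest possible, and an adjusted p of 0.107. By that exact permutation test 0 of the 27 lists had an adjusted p under 0.05, with 8 at an unadjusted p under 0.05, against 21 and 22 between bovine and ovine controls. The endothelial markers, though called by camera, were not among those 8 (exact permutation p = 0.175). Whether a list at the smallest p passes over 27 lists depends on how many others reach it, so the adjusted values do not decide the hypothesis for the 2 that separated.

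Probe sets with a sub-cluster number of 2 or more in their identifier made up 14 of the 35 that rose with GW9662 (40%) and 18.0% of those that did not change (two-sided Fisher exact p = 0.00286), against 1 of the 9 that fell (11.1%, Fisher exact p = 1). With 1 rising probe set per cluster, since SRSF1 has 2 among the 14, p was 0.00464, and with dim probe sets left out as well it was 0.000350. These tests reuse the probe sets that prompted the question, so they do not decide whether a chance draw made the pattern. Within 283 genes with both kinds, the GW9662 difference was higher on the secondary probe sets in 168, by a median of 0.04, and the secondary ones were dimmer by a median of -0.82. A candidate explanation is that they lie at other places along the transcript, where RNA quality acts differently, but no probe positions were at hand to test it.

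A second hypothesis was that GW9662 effects run opposite to an axis of array or RNA quality on which vehicle replicate 1 lies far out. Across 7391 bright probe sets, with no vehicle array used on both sides, the deviation of replicate 1 correlated with the GW9662 effect at a median r of -0.255 (-0.431 to -0.153 over 6 splits), in the direction needed. Vehicle replicate 2 gave a median of -0.312 and replicates 3, 4 and 5 gave 0.113, 0.393 and 0.222, so replicate 1 was not the most opposed array, and the hypothesis could not be decided.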
